A study of Mus musculus with 6 samples.

How the data were processed

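Spinal cords of wild-type mice and of mice carrying a mutant SOD1 transgene, a model of amyotrophic lateral sclerosis, were profiled by Drop-seq, a droplet method that tags the RNA of single cells with a cell barcode and a unique molecular identifier (UMI). Per the labels, the tissue was digested with the enzyme mix Accutase and freed of myelin, and live cells came from a density gradient of OptiPrep in Hibernate A. The mice received vehicle or Necrostatin-1s, an inhibitor of the kinase RIPK1. The 6 libraries fell into 3 groups of 2: wild-type with vehicle (WT-Veh), SOD1 mutant with vehicle (SOD1-Veh) and SOD1 mutant with Necrostatin-1s (SOD1-Nec). The labels do not say whether the libraries of a group come from separate animals, so the p-values measure the spread between these libraries alone.

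The deposited tables hold UMI counts per gene symbol and cell barcode, 1 table per library, with no normalization. The values were checked to be whole numbers under barcodes of 12 bases. The submitters' processing notes name the genome build mm9; the aligner and the gene annotation are not given in the sources used here. The tables numbered replicate 1 in each group list 18169 genes and those numbered replicate 2 list 18650, so each set of 3 tables was listed together. The 17042 genes in all tables were used. No other batch is named in the labels. Gene positions are not given, because the tables hold symbols without coordinates.

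The tables held 21919 barcodes. Barcodes were retained with at least 200 detected genes and at most 20% of UMIs from mitochondrially encoded genes, which left 3360. Scrublet, run per library in scanpy 1.11.5 with an automatic threshold, marked 16 of them as doublets, and the 3344 others were kept. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered over 15 nearest neighbours by Leiden (leidenalg 0.10.2) at resolution 1, without integration of libraries. Marker lists fixed before the data were examined gave names to 17 of the 18 clusters, in 13 classes. Class names below stand for such marker-based, cell-like classes. The cluster left without a name was led by skeletal muscle genes.

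UMI counts were summed per library over all retained cells and over each class with at least 20 cells in every library, which held for microglia, B cells, erythroid cells, monocytes and neutrophils. Sums were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the filterByExpr minimum, in a single fit of the 6 libraries with the group as the only term. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Levels are normalised counts in the CPM unit of edgeR, with the SD over 2 libraries, fold changes are fitted by edgeR, and log2 fold changes carry their standard error. Where a group held no UMI of a gene, the fold was bounded with a floor of 3 counts over the group; with 1 to 3 counts the ratio of summed counts is given with its exact 95% interval. Intervals and floors cover counting error only.

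Before the data were examined, 29 gene lists were written for the cell states and pathways of this tissue. Of their 631 symbols, 615 were in the tables as written, 6 matched by a synonym and 10 did not match. Each list with at least 5 tested members, 17 of the lists in microglia, was compared with the other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 on voom values, and p-values were adjusted over lists. No list call of any comparison held when the correlation was estimated from the data; those adjusted p-values stand beside the calls. List medians are also given for each set of tables, first the 3 libraries numbered 1, then those numbered 2. Class shares were tested with edgeR on cell counts, with the cell total of a library as the offset.

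Every comparison rests on 2 libraries against 2. An exact permutation test cannot go below p = 0.333 in this design, so the models above were used. The shares of microglia with a UMI of 10 inflammatory and disease-associated genes were described without a test, after thinning each cell to 500 UMIs. The genotype and treatment effects share the SOD1-Veh libraries, so their covariance and correlation over genes were set against 100 simulated sets of unchanged groups that share them too. The RNA of barcodes with under 100 genes was taken as the free RNA of a library; for an alternative it was scaled by the haemoglobin UMIs of microglia and subtracted.

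Genes were named by a rule written before the data were examined. It takes up to 8 rising and 8 falling genes with the largest change among called genes whose libraries did not overlap, and up to 3 members of each list with the smallest p. Where fewer than 10 genes passed, it adds the 4 rising and 4 falling genes with the smallest p. Sod1, Ripk1, Ripk3, Mlkl, Tnf, Il1a, Il1b, Apoe and Trem2 are always looked up, and in other classes up to 3 called genes are taken in each direction. Predicted, ribosomal protein and mitochondrial genes were passed over in naming and stayed in every count. Not every gene that the rule allows is named. Genes chosen after their values were seen are described so.

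The tests were tested on simulated data with the dispersion of these libraries, as 10 sets of 200 changed genes. In microglia edgeR recovered 37.9% of genes changed 2-fold and 86.2% of those changed 4-fold, with 3.56% of calls false. In all cells it recovered 8.24% and 66.7%, with 7.20% of calls false. The share test recovered a 4-fold rise of 1 class, astrocytes in SOD1-Veh, in 80.0% of 10 sets, but 27.3% of its calls were false, so share calls are loose. Other classes and falls were not simulated.

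The alternatives were DESeq2 1.42.0, no low-count filter, the replicate number as a block, a fit of the 4 libraries compared, each library left out in turn, doublets kept, at least 400 genes per cell, Leiden resolution 0.5, an estimated inter-gene correlation, fry, TMM factors over classes and thinning to 300 UMIs. Chosen after seeing the data were at least 100 genes per cell, up to 40% mitochondrial UMIs, free RNA subtracted, every barcode, neural and vascular classes only, all cells without the unnamed cluster, and a crossed replicate block.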

Results

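The data were Drop-seq UMI counts from single spinal cord cells, in 6 libraries of 2 per group. Total UMIs were 1727658 and 1628385 in the WT-Veh libraries, 1585172 and 1508618 in SOD1-Veh, and 1767205 and 1671506 in SOD1-Nec. The retained cells numbered 512 and 549 in WT-Veh, 397 and 432 in SOD1-Veh, and 661 and 793 in SOD1-Nec. Their median depth was 655 and 576 UMIs per cell in WT-Veh, 727 and 697 in SOD1-Veh, and 528 and 526 in SOD1-Nec. Cells were shallow, so libraries were compared by summed counts, which ranged from 432928 to 652290 UMIs over all retained cells and from 69140 to 100058 UMIs over microglia. The mitochondrial limit removed 31.3% and 31.6% of barcodes with at least 200 genes in WT-Veh, 40.9% and 33.3% in SOD1-Veh, and 25.1% and 19.1% in SOD1-Nec. The tables hold a single Sod1 entry, which does not separate reads of the human transgene from those of the mouse gene. Over all barcodes Sod1 reached 213 and 179 CPM in WT-Veh, 4137 and 5310 in SOD1-Veh, and 4446 and 5387 in SOD1-Nec.

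Microglia, the resident macrophages of the cord, made up a like share of cells in every group: 18.7% ± 1.99 in WT-Veh, 19.7% ± 2.37 in SOD1-Veh and 18.9% ± 1.07 in SOD1-Nec (SD, n = 2). Marrow- and blood-type cells were abundant. B cells made up 8.55% ± 2.55, 17.8% ± 3.03 and 18.3% ± 1.93 of cells in the same order, monocytes 8.27% ± 2.94, 6.88% ± 0.240 and 13.1% ± 0.515, erythroid cells 11.7%, 14.2% and 17.6%, and neutrophils 14.5%, 12.2% and 10.9%. Astrocytes, which support neurons and clear glutamate, were 5.75% ± 0.150 of WT-Veh cells, 4.86% ± 1.31 of SOD1-Veh cells and 1.77% ± 0.357 of SOD1-Nec cells, and oligodendrocytes were 5.30%, 5.50% and 7.35%. With doublets kept, astrocytes were instead 10.2%, 9.78% and 8.85% of cells in the same order, and erythroid cells 6.70%, 8.95% and 9.32%. These classes moved in opposite directions with the clustering, so both shares depend on it, and erythroid gene results may too. Neuron-like cells were 6.64% of the first WT-Veh library and 29.7% of the second, against means of 2.45% ± 1.17 in SOD1-Veh and 2.67% ± 2.00 in SOD1-Nec. The unnamed cluster, led by skeletal muscle genes, held 7.81% ± 4.99 of SOD1-Veh cells and no cell of the other groups. In the edgeR test, the share of astrocytes fell between WT-Veh and SOD1-Nec (log2 fold change -1.68 ± 0.34, adjusted p = 0.0437) and the unnamed cluster was lower in SOD1-Nec than in SOD1-Veh (adjusted p = 0.0453). The same test of astrocytes between SOD1-Veh and SOD1-Nec gave -1.44 ± 0.36 with adjusted p = 0.0525. No class passed between SOD1-Veh and WT-Veh, where 3 classes had an unadjusted p below 0.05; B cells gave 1.06 ± 0.33 with adjusted p = 0.109. The astrocyte call was lost without WT-Veh 2 (-1.70), SOD1-Nec 1 (-1.50) or SOD1-Nec 2 (-1.91), with the replicate number as a block (-1.68), with at least 400 genes per cell (-1.05), with doublets kept (-0.21) and among neural and vascular cells alone (-1.20). It was kept with TMM factors over classes and with up to 40% mitochondrial UMIs, and at least 100 genes per cell and Leiden resolution 0.5 gave no astrocyte class. Calls in that comparison numbered 5 without WT-Veh 1 and 0 without WT-Veh 2 or SOD1-Nec 2, where edgeR gave 3 classes an unadjusted p below 0.05 each time; no other tool was run on shares. The call of the unnamed cluster was lost without SOD1-Veh 1 (-9.07) or SOD1-Veh 2 (-7.65), with TMM factors (-8.56) and with at least 400 (-1.09) or 100 genes per cell (0.09).

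**Figure D1:**
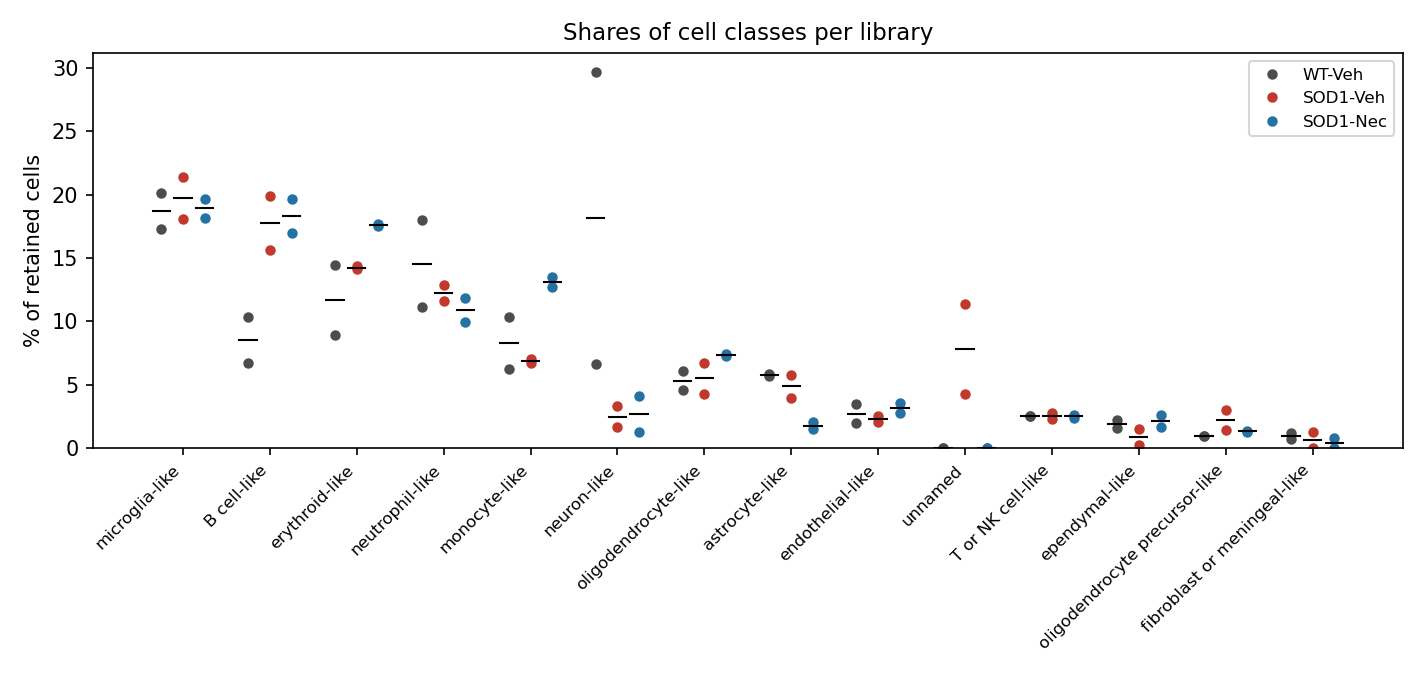
Share of retained cells (%) in each class for each library, shown as dots per group with a line at the mean of 2 libraries. Microglia lie between 18.7% and 19.7% on average in all groups, and the unnamed cluster appears in SOD1-Veh alone.

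The comparison of SOD1-Veh with WT-Veh asks which genes differ with the mutant transgene under vehicle. Microglia of SOD1-Veh cords had more RNA of Apoe, a lipid carrier, Lpl, a lipase that releases fatty acids, Lgals3, a galactose-binding lectin, Spp1, which encodes osteopontin, and Cd63, a membrane protein of late endosomes and lysosomes. Csf1, a growth factor for macrophages, the chemokines Ccl4 and Ccl6, the iron-storage subunit Ftl1, the lysosomal protease Ctsb and the lysozyme Lyz2 rose with them, while Siglech, a surface lectin of resting microglia, fell. Apoe was 5.57-fold higher, at 4895 ± 1052 CPM against 879 ± 199 (SD, n = 2), Lpl 7.43-fold higher at 493 ± 120 against 68.0 ± 96.1, Cd63 4.45-fold higher at 1614 ± 24.0 against 357 ± 121, and Siglech 1.99-fold lower at 1281 ± 124 against 2565 ± 266. In all, 19 genes rose and 7 fell of 1585 tested in microglia, and the libraries of the groups did not overlap for any called gene named here.

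The 21 tested disease-associated microglia genes formed the list with the smallest p: 11 rose, none fell, and the median log2 fold change was 1.00, with 1.04 in the first set of tables and 0.87 in the second (camera adjusted p = 3.1e-19; adjusted p = 0.125 with an estimated correlation). Adjusted over the list alone, 13 rose. Apoe rose by a log2 fold change of 2.48 ± 0.26 (adjusted p = 9.4e-12), Cd63 by 2.15 ± 0.27 (7.9e-09), Lpl by 2.89 ± 0.51 (3.86e-05) and Csf1 by 2.13 ± 0.43 (0.000536). Lgals3 and Spp1 had few UMIs in WT-Veh, with a ratio of counts of 41.5 (95% interval 11.1 to 348) and 20.5 (5.30 to 175). Trem2, a lipid-sensing receptor of the list, gave 0.01 with adjusted p = 0.980. The 5 cholesterol efflux and lipid droplet genes, which share Apoe and Lpl, rose (median 1.00, 1.58 and 0.67 by set, adjusted p = 7.9e-04, and 0.237 with an estimated correlation), with 2 called over all genes and 2 adjusted over the list alone.

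Of the 26 homeostatic genes of resting microglia, Siglech fell (-0.99 ± 0.22, adjusted p = 0.00308) and the list was lower as a whole (median -0.39, -0.37 and -0.34 by set, adjusted p = 4.8e-05, and 0.125 with an estimated correlation), with 2 falling adjusted over the list alone. Tmem119, another marker of these cells, gave -0.62 with adjusted p = 0.208. The TNF and NF-kB inflammatory list rose (21 genes, median 0.32, 0.12 and 0.47 by set, adjusted p = 0.0021, and 0.400 with an estimated correlation). Ccl4 was its 1 call (1.19 ± 0.22, adjusted p = 7.69e-05; 6387 ± 1801 CPM against 2801 ± 557) and 2 rose adjusted over the list alone; Ccl3 gave 0.69 (0.0655), Tnf 0.69 ± 0.30 (0.352), Il1a 0.27 (0.795) and Il1b -1.60 (0.568). Lysosome genes rose (24 genes, median 0.16, 0.14 and 0.26 by set, adjusted p = 0.0158, and 0.451 with an estimated correlation) with Ctsb as the call (0.91 ± 0.21, 0.00387) and 4 adjusted over the list alone. The antioxidant and iron list passed (adjusted p = 0.0437, and 0.604 with an estimated correlation) through its members Sod1 and Ftl1: its 8 genes had a median of 0.03 but a mean of 0.47, its set medians were -0.50 and 0.43, and adjusted over the list alone 2 rose and 1 fell. Sod1, the gene of the transgene, was 15.5-fold higher (3.95 ± 0.31, adjusted p = 1.62e-16), and Ftl1 2.80-fold higher (1.48 ± 0.23, 2.07e-06).

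Lists not past the test were glycolysis (adjusted p = 0.0730, median 0.65, 7 of 7 genes positive), oxidative phosphorylation (0.107), myelin (0.229), complement (0.248), astrocyte function (0.248), immediate-early genes (0.385, median -0.03), the unfolded protein response (0.385), MHC class I (0.791; median -0.07, mean 0.04), cell division (0.883), stressed oligodendrocyte (0.883) and heat shock (0.939; median 0.06, mean -0.01). Red cell RNA moved with these groups: Hba-a1, an alpha chain of haemoglobin, fell (-2.56, adjusted p = 6.69e-12), as did Hbb-bs (-2.17, 1.01e-10), and haemoglobin took 2.33% and 1.62% of microglial UMIs in WT-Veh against 0.277% and 0.532% in SOD1-Veh. Meg3, a long non-coding RNA abundant in neurons, was 16.1-fold lower (adjusted p = 1.46e-08). The calls of Siglech and Ctsb were lost without WT-Veh 1 (-0.88 and 0.84), Csf1 without WT-Veh 2 (1.78), Ccl6 without SOD1-Veh 2 (1.16) and Lyz2 (1.27) in 8 alternatives, among them without either WT-Veh library (1.25 and 1.30) or SOD1-Veh 1 (1.13). Without WT-Veh 1, no WT-Veh UMI of Lpl or Lgals3 was left and they were at least 3.45 and 3.89, and without WT-Veh 2 they were 1.83 and 4.17. Spp1 was 3.33 without WT-Veh 1 and, with no WT-Veh UMI left, at least 2.67 without WT-Veh 2; it was 2.17 and no longer called without SOD1-Veh 1 and 4.85 without SOD1-Veh 2, and DESeq2 called neither Spp1 (adjusted p = 0.254), Lpl (0.662) nor Ccl6 (0.0749); Meg3 was -3.39, -3.14 and -5.43 without WT-Veh 2, SOD1-Veh 1 and SOD1-Veh 2.

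**Figure D2:**
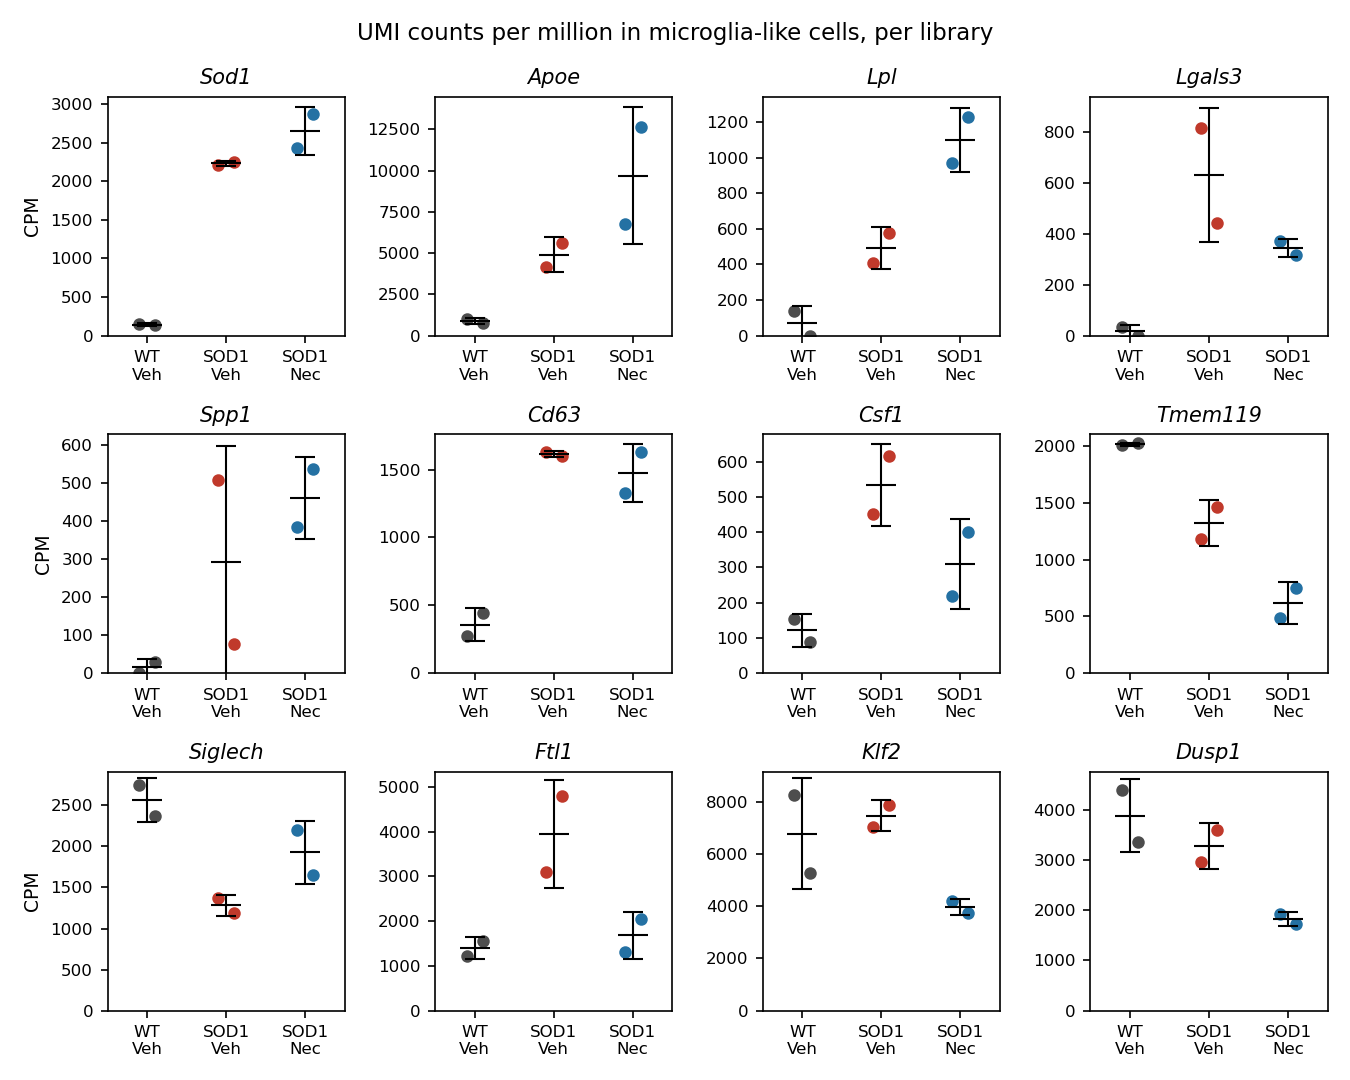
Normalised level (CPM) of 12 genes in microglia, as dots per library with the mean and SD bars of each group (n = 2). Apoe lies at 879 CPM on average in WT-Veh, 4895 in SOD1-Veh and 9685 in SOD1-Nec, whereas Tmem119 falls to 616 in SOD1-Nec and Ftl1 is highest in SOD1-Veh, at 3940.

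Over all cells, microglia included, differences between SOD1-Veh and WT-Veh included the transgene, skeletal muscle RNA and neuronal RNA. In all 50 genes rose and 13 fell of 7494 tested. Myl1, a myosin light chain, was at least 1054-fold higher, at 3084 ± 1419 CPM against no UMI in WT-Veh (adjusted p = 1.27e-06); Acta1, the skeletal actin, was at least 978-fold and Ckm, the muscle creatine kinase, at least 618-fold higher. DESeq2 called none of these 3 genes (adjusted p = 0.366, 0.379 and 0.499). The muscle RNA came mostly from the unnamed cluster, 17 and 49 cells of the SOD1-Veh libraries, so differences of dissection are not separated from genotype. Aldoa, a glycolytic enzyme abundant in muscle, rose 6.83-fold (adjusted p = 0.000324). Sod1 rose 23.4-fold (2.18e-06), Lpl 9.59-fold (0.00519) and Ccl4 2.41-fold (0.0400), while Apoe gave 0.84 (0.314), Tnf 0.89 (0.370), Il1a 0.41 (0.701), Il1b -0.81 (0.513), Ripk1 0.18 (0.943) and Trem2 0.19 (0.881). Among neuronal RNAs, Meg3 fell 15.7-fold (142 ± 13.1 CPM against 2235 ± 1960, adjusted p = 0.00218), Miat 21.3-fold (0.00227), Snhg11 14.1-fold (0.00381) and the synaptic vesicle gene Sv2a by 2.33 on the log2 scale (0.0330). The neuron list held 15 tested genes, of which 2 fell over all genes and 2 adjusted over the list alone (median -1.06, -0.30 and -1.40 by set). Apod, a lipocalin, also fell (-1.52, 0.0277). These counts rest on the muscle cluster and on single libraries: 6 genes were called without the unnamed cluster, 161 without WT-Veh 1, 24 without WT-Veh 2 and 29 without SOD1-Veh 2. Without WT-Veh 2, the library rich in neuron-like cells, Meg3 was -2.59, and Miat (-3.42), Snhg11 (-2.42), Sv2a (-1.68), Apod (-1.29), Lpl (2.44) and Ccl4 (1.14) were no longer called.

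Sod1 rose in each of the other tested classes, by 3.65 in B cells (adjusted p = 0.00272), 5.26 in erythroid cells (2.31e-10), 2.89 in monocytes (3.39e-07) and 3.88 in neutrophils (0.00218). In monocytes, S100a9, a calcium-binding protein of neutrophils and immature myeloid cells, was 48.1-fold lower in SOD1-Veh (230 ± 162 CPM against 10581 ± 1615, adjusted p = 4.1e-11), and Camp, a granule peptide of neutrophil precursors, had a ratio of counts of 0.0237 (0.00485 to 0.0704; adjusted p = 5.68e-08). Apol11b fell in erythroid cells (-2.58, adjusted p = 0.0251), as did Meg3 (-3.44, 0.0214). The other classes gave 19 calls in all, and 56 without SOD1-Veh 1 and 29 without WT-Veh 1. Without WT-Veh 1, Sod1 was 4.84 in B cells and 5.00 in neutrophils; without SOD1-Veh 2 it was 3.01 in B cells, and S100a9 and Camp were -6.52 and -6.19 in monocytes; without WT-Veh 2, Apol11b was -1.98 and Meg3 -2.22, and Meg3 was -4.21 without WT-Veh 1.

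The comparison of SOD1-Nec with SOD1-Veh asks what differs with the RIPK1 inhibitor in mutant cords. In microglia, Apoe and Lpl were higher still after Necrostatin-1s, whereas Ftl1, Tmem119, a microglial membrane protein, and a set of immediate-early genes were lower. These were Klf2 and Klf6, zinc-finger transcription factors, Dusp1, a phosphatase that switches off MAP kinases, and Socs3, a brake on cytokine signalling. The polyubiquitin gene Ubb fell with them, and Mt2, a metal-binding metallothionein, rose. Apoe was 1.99-fold higher, at 9685 ± 4157 CPM against 4895 ± 1052 (SD, n = 2), Lpl 2.27-fold higher at 1101 ± 180 against 493 ± 120, Ftl1 2.31-fold lower at 1682 ± 528 against 3940 ± 1205 and Klf2 1.88-fold lower at 3974 ± 313 against 7471 ± 595. Of 1585 genes tested, 40 rose and 19 fell, against 36, 39 and 35 calls in all without SOD1-Veh 2, SOD1-Nec 1 and SOD1-Nec 2.

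Among 21 immediate-early and dissociation response genes, 5 fell and none rose, and 11 fell adjusted over the list alone (median -0.56, -0.41 and -0.55 by set, camera adjusted p = 4.4e-09, and 0.276 with an estimated correlation). Klf2 fell by 0.91 ± 0.21 on the log2 scale (adjusted p = 0.00346), Dusp1 by 0.84 ± 0.22 (0.0101), Socs3 by 0.84 (0.0297) and Klf6 by 0.73 (0.0297), while Fos gave -0.38 (0.412). The cluster of microglia led by Ccl3 and Ccl4, with Atf3, Egr1, Jun and Socs3 among its 10 leading genes, held 46 of 85 and 39 of 78 microglia in SOD1-Veh, and 34 of 120 and 28 of 156 in SOD1-Nec. Genes of this list helped to form the cluster, so its smaller share is no separate result. Depth differed too, since 139 of 276 SOD1-Nec microglia had under 500 UMIs, against 45 of 163 in SOD1-Veh. The TNF and NF-kB list fell (median -0.29, -0.22 and -0.32 by set, adjusted p = 0.0125, and 0.286 with an estimated correlation) with Socs3 called over all genes and, adjusted over the list alone, 3 falling and 1 rising. Its cytokines did not pass: Il1a gave -0.91 ± 0.30 (438 ± 122 CPM against 845 ± 165, adjusted p = 0.0696), Tnf -0.42 ± 0.29 (0.579) and Il1b 2.44 ± 0.88 (0.106). The heat shock list (11 genes, median -0.03, -0.09 and -0.79 by set, adjusted p = 0.0390, and 0.276 with an estimated correlation) held Ubb (-1.15, 0.00031), with 3 falling adjusted over the list alone.

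Complement genes fell as a list with no member called (8 genes, median -0.39, -0.22 and -0.56 by set, adjusted p = 0.0125, and 0.286 with an estimated correlation); C1qa, which starts the classical cascade, gave -0.59 (0.105). Homeostatic genes fell further (26 genes, median -0.16, -0.23 and -0.20 by set, adjusted p = 0.0390, and 0.276 with an estimated correlation) with Tmem119 as the call, 2.10-fold lower (616 ± 183 CPM against 1321 ± 200, adjusted p = 0.00503), also the 1 call adjusted over the list alone. Lysosome genes fell without a called member (median -0.20, -0.13 and -0.13 by set, adjusted p = 0.0390, and 0.377 with an estimated correlation), as did stressed oligodendrocyte genes, again with Socs3 called (7 genes, median -0.38, -0.31 and -0.45 by set, 0.0311, and 0.276 with an estimated correlation). Cholesterol efflux genes rose through Apoe (0.99 ± 0.22, 0.00194) and Lpl (1.18 ± 0.31, 0.0113), which were also the 2 calls adjusted over the list alone (median 0.99, 0.70 and 1.09 by set, list adjusted p = 0.0036, and 0.276 with an estimated correlation). Genes of oxidative phosphorylation rose as a list, 23 of 28 being positive and none called (median 0.37, 0.31 and 0.44 by set, adjusted p = 0.0125, and 0.276 with an estimated correlation). Myelin genes also rose (6 genes, median 0.39, 0.34 and 0.42 by set, 0.0390, and 0.427 with an estimated correlation), with 3 adjusted over the list alone.

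The number of lists past the test was 10, and 5 without SOD1-Veh 1. With the replicate number as a block it was 6, and the homeostatic (adjusted p = 0.0676), lysosome (0.0689), myelin (0.0689) and heat shock (0.0919) lists no longer passed. The disease-associated list as a whole did not pass (adjusted p = 0.877; 2 rose; median -0.12, mean 0.10), and Trem2 (-0.25, 0.664) and Sod1 (0.25, 0.656) were not called. The unfolded protein response (0.336), astrocyte function (0.363), antioxidant and iron (0.628), glycolysis (0.921), MHC class I (0.929) and cell division (0.937; median 0.09, mean -0.02) lists did not pass either. RNA of other cells moved with these groups in microglia: Hba-a1 was 14.1-fold higher (adjusted p = 9.61e-20), haemoglobin took 4.51% and 3.33% of microglial UMIs in SOD1-Nec against 0.277% and 0.532% in SOD1-Veh, and the neutrophil gene S100a8 fell by 1.84 (0.000869). Apoe was 0.79 without SOD1-Veh 1 and 0.44 without SOD1-Nec 2, and Lpl 0.94 and 0.98, neither then called nor called by DESeq2 (adjusted p = 0.180 and 0.731); Tmem119 (-0.92 and -0.82), Dusp1 (-0.70 and -0.93) and Klf6 (-0.64 and -0.58) were lost without SOD1-Veh 2 or SOD1-Nec 1, Dusp1 and Klf2 without SOD1-Nec 2 (-0.78 and -0.85), and Ubb without SOD1-Veh 2 (-0.82). Socs3 (-0.88 to -0.84) was lost without each library of this comparison, Mt2 without SOD1-Veh 1 (1.35) and SOD1-Nec 1 (1.24), S100a8 without SOD1-Veh 1 (-1.10), and with at least 400 genes per cell S100a8 was -0.06.

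Over all cells, Necrostatin-1s libraries lacked the muscle RNA of SOD1-Veh, and little else passed. That RNA came mostly from the unnamed cluster of SOD1-Veh, so differences of dissection are not separated from treatment. Of the 44 called genes (24 without SOD1-Veh 2) 43 were lower in SOD1-Nec, among them Myl1 (at least 1175-fold lower, adjusted p = 1.09e-06), Acta1 (at least 1091-fold), Tnnc2, a troponin of fast muscle (at least 873-fold), Ckm (at least 689-fold) and Aldoa (7.69-fold, 0.00019). DESeq2 did not call Myl1, Acta1, Tnnc2 or Ckm (0.544, 0.568, 0.626 and 0.673). Without the unnamed cluster, edgeR called 0 genes, with 471 at an unadjusted p below 0.05; DESeq2 was not run on that setting and called 33 with the cluster kept. Il1a gave -1.09 (0.290), Tnf -0.76 (0.701), Trem2 -0.44 (0.833), Sod1 -0.30 (0.874), Ripk1 -0.14 (0.974), Apoe 0.08 (0.974) and Il1b 0.44 (0.869). In monocytes, S100a9 rose 21.0-fold, to 4629 ± 486 CPM from 230 ± 162 (adjusted p = 3.38e-08), and Camp had a ratio of counts of 34.5 (11.6 to 169; 2.64e-07), while Hba-a1 rose by 3.45 (1.28e-07). In erythroid cells, Bnip3l, a mitophagy receptor of maturing red cells, fell (-1.89, 0.00655), as did Ftl1 (-1.56, 0.00665), and the elongation factor Eef1b2 rose (1.53, 0.0200). Neutrophils gave 0 calls by edgeR, with 91 genes at an unadjusted p below 0.05, and 0 by DESeq2. The other classes gave 33 calls, with 103 without SOD1-Veh 1 and 50 without SOD1-Veh 2; without SOD1-Veh 2, S100a9 was 5.36 and Camp 5.79 in monocytes, and Eef1b2 (1.45) was no longer called. Without SOD1-Nec 1, Bnip3l (-1.73), Ftl1 (-1.48) and Eef1b2 (1.53) were lost, and Eef1b2 (1.44) without SOD1-Nec 2.

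The comparison of SOD1-Nec with WT-Veh asks which differences from wild type are present in mutant cords given the inhibitor. Treated mutant microglia had high Apoe, Lpl, Spp1, Lgals3, Cd63, Lyz2 and Ctsb, and also more Cd74, the invariant chain of MHC class II. They had less Tmem119, Selplg, an adhesion ligand, Csf1r, the receptor on which microglia depend, and C1qa, and less of the immediate-early transcription factors Jun and Fos. Apoe was 11.1-fold higher, at 9685 ± 4157 CPM against 879 ± 199 (SD, n = 2), and Lpl 16.9-fold higher, whereas Tmem119 was 3.22-fold lower, at 616 ± 183 CPM against 2014 ± 12.5. Of 1585 genes, 58 rose and 40 fell, against 64 calls in all without WT-Veh 1 and 42 without SOD1-Nec 2.

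Of the 21 disease-associated genes 9 rose and none fell, with 13 rising adjusted over the list alone (median 0.98, 0.73 and 0.94 by set, camera adjusted p = 2.8e-12, and 0.128 with an estimated correlation). Apoe gave 3.47 ± 0.26 (adjusted p = 3.32e-18), Lpl 4.08 ± 0.44 (7.05e-11), Cd63 2.03 (1.06e-07) and Lyz2 1.88 (7.77e-06). The ratio of counts was 29.7 (7.88 to 251) for Spp1 and 21.6 (5.63 to 183) for Lgals3. Ftl1, by contrast, gave 0.28 with adjusted p = 0.569. Of the 26 homeostatic genes 5 fell, and 11 adjusted over the list alone (median -0.51, -0.54 and -0.68 by set, 7.3e-08, and 0.128 with an estimated correlation): Tmem119 fell by 1.69 ± 0.25 (7.21e-07), Selplg by 1.12 (0.000272) and Csf1r by 0.85 (0.00499). Cholesterol efflux genes rose (median 2.91, 2.72 and 1.99 by set, 6.1e-06, and 0.128 with an estimated correlation), with 2 called and 3 adjusted over the list alone. Complement genes fell (median -0.52, -0.56 and -0.50 by set, 4.6e-04, and 0.209 with an estimated correlation), with C1qa called (-1.07, 0.000273) and 2 adjusted over the list alone.

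Immediate-early genes fell, 6 of 21 being called and 16 adjusted over the list alone (median -0.59, -0.77 and -0.41 by set, adjusted p = 2.9e-10, and 0.209 with an estimated correlation). Dusp1 was 2.12-fold lower (0.000305), Jun 2.04-fold (0.000308) and Fos 1.75-fold (0.00718). The microglia cluster led by Ccl3 and Ccl4 held 44 of 103 and 50 of 95 microglia in WT-Veh, against 34 of 120 and 28 of 156 in SOD1-Nec. This share is no separate result either, since immediate-early genes helped to form the cluster. Of WT-Veh microglia, 65 of 198 had under 500 UMIs, against 139 of 276 in SOD1-Nec. Genes of oxidative phosphorylation were positive in 28 of 28 and none was called (median 0.61, 0.50 and 0.70 by set, 2.4e-05, and 0.144 with an estimated correlation). In the other classes the list was positive too, but lower and not tested: the median was 0.44 in B cells, 0.15 in erythroid cells, 0.20 in monocytes and 0.17 in neutrophils. Ribosomal protein genes, a set chosen after the data were seen, had a median of 0.60 in microglia in this comparison. Myelin genes rose (median 0.60, 0.25 and 0.68 by set, 9.98e-04, and 0.234 with an estimated correlation), with Mbp 1.77-fold higher and 2 calls adjusted over the list alone. The antioxidant and iron list passed through Sod1, its 1 call in both adjustments (median 0.27, -0.06 and 0.71 by set, 0.0222, and 0.420 with an estimated correlation), and heat shock genes fell (median -0.23, -0.25 and -0.34 by set, 0.0463, and 0.234 with an estimated correlation) with Ubb called and 3 adjusted over the list alone. Ccl4 was 1.94-fold higher (0.00165), while Tnf gave 0.27 (0.701), Il1a -0.64 (0.213), Il1b 0.84 (0.549) and Trem2 -0.23 (0.600). The stressed oligodendrocyte (0.0576), glycolysis (0.0672), unfolded protein response (0.0672), TNF and NF-kB (0.902), lysosome (0.902), MHC class I (0.902; median -0.09, mean 0.14), cell division (0.970) and astrocyte function (0.970; median 0.30, mean -0.12) lists did not pass. Hba-a1 rose by 1.27 (3.39e-05) beside these groups. Without WT-Veh 1, no WT-Veh UMI of Lpl or Lgals3 was left and they were at least 4.66 and 2.95, and without WT-Veh 2 they were 3.03 and 3.28. Spp1 was 3.90 without WT-Veh 1 and, with no WT-Veh UMI left, at least 3.23 without WT-Veh 2; Cd74 was lost without WT-Veh 1, WT-Veh 2 or SOD1-Nec 2 (2.27, 2.64 and 2.42) and was -0.32 with up to 40% mitochondrial UMIs. With at least 400 genes per cell Mbp (0.37) was not called. Fos was lost without WT-Veh 1 (-0.54), SOD1-Nec 1 (-0.80) or SOD1-Nec 2 (-0.78), Csf1r without SOD1-Nec 2 (-0.76), Mbp without WT-Veh 2 (0.58) or SOD1-Nec 2 (0.71), and Ubb without WT-Veh 1 (-0.74) or either SOD1-Nec library (-0.86 and -0.78).

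**Figure D3:**
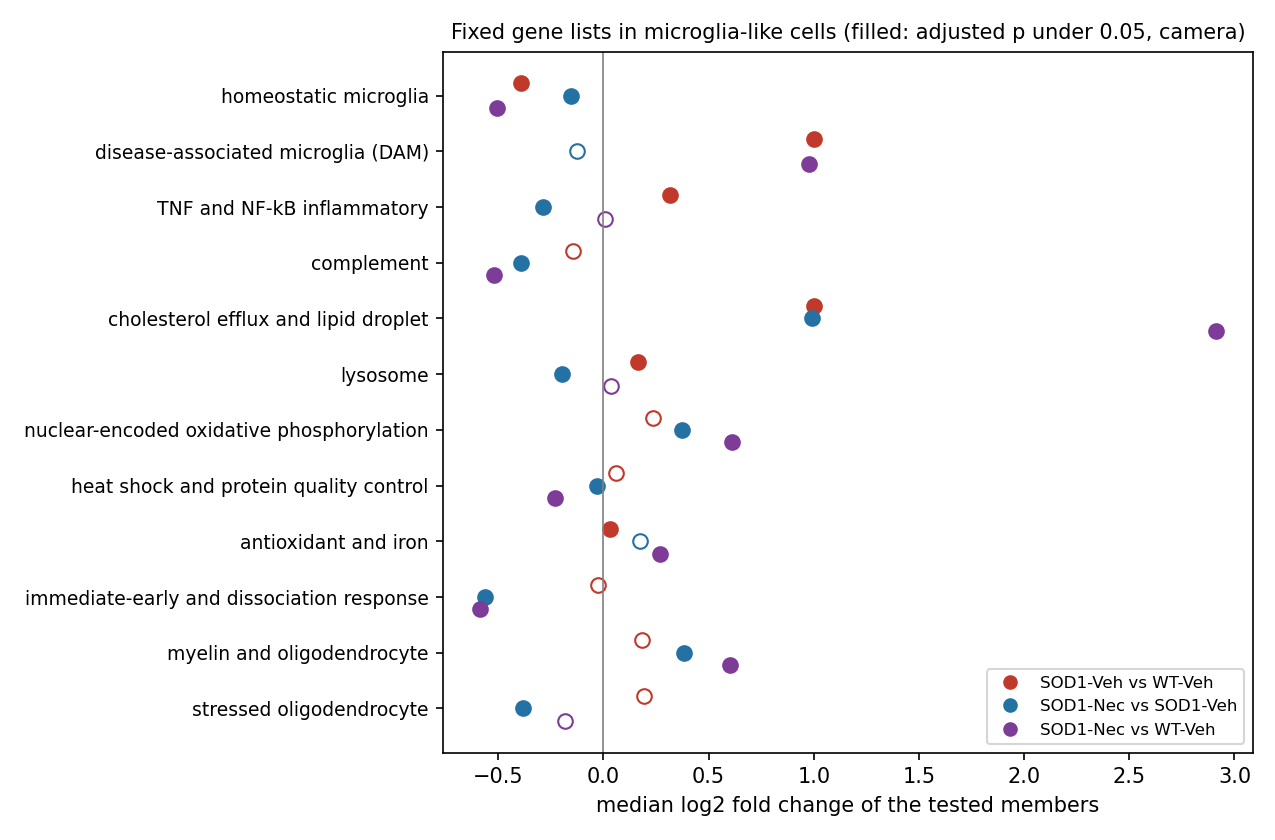
Median log2 fold change of 12 gene lists in microglia in the 3 comparisons, with filled symbols where camera with a preset correlation gave an adjusted p below 0.05. The disease-associated list stands at 1.00, -0.12 and 0.98, and the immediate-early list at -0.03, -0.56 and -0.59, in SOD1-Veh against WT-Veh, SOD1-Nec against SOD1-Veh and SOD1-Nec against WT-Veh.

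Over all cells, 3 genes differed between SOD1-Nec and WT-Veh. Sod1 rose 19.0-fold (adjusted p = 2.89e-05), Lpl rose to 159 ± 4.64 CPM from 9.63 ± 10.8 (0.00531), and Miat, a long non-coding RNA of neurons, fell 16.5-fold (0.0221). Apoe gave 0.92 (0.428), Tnf 0.13 (0.950), Il1a -0.68 (0.587), Il1b -0.37 (0.818), Ripk1 0.04 (0.993) and Trem2 -0.24 (0.852). Sod1 rose in B cells (3.51, 0.00414), erythroid cells (4.42, 3.66e-09), monocytes (2.81, 1.2e-06) and neutrophils (3.86, 0.00201). In erythroid cells, Apol11b fell by 2.95 (0.00205) and Bcl2l1, a survival factor of the BCL2 family, by 2.66 (0.0305). The other classes gave 41 calls, with 64 without WT-Veh 1 and 25 without WT-Veh 2. The count of 3 became 53, 1 and 12 without WT-Veh 1, WT-Veh 2 and SOD1-Nec 1, Lpl was 6.17 without WT-Veh 1 and lost without WT-Veh 2 (3.18), and Miat was lost without WT-Veh 2 (-3.04) or SOD1-Nec 2 (-3.44) and was -4.92 without SOD1-Nec 1. Without WT-Veh 1, Sod1 was 4.72 in B cells and 5.03 in neutrophils and Bcl2l1 -3.33; Bcl2l1 was lost without WT-Veh 2 (-1.99) or SOD1-Nec 1 (-2.53), and Apol11b was -4.01 without SOD1-Nec 2.

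Ripk1, the target of the inhibitor, was barely sampled. Microglia held 9 and 3 Ripk1 UMIs in WT-Veh, 4 and 4 in SOD1-Veh, and 1 and 9 in SOD1-Nec, and the genes of its necroptosis partners Ripk3 and Mlkl held at most 1 UMI per library, so differences in them were not detectable in microglia at this depth. A further 12 lists had fewer than 5 tested members in microglia, and their medians are given for SOD1-Veh against WT-Veh, SOD1-Nec against SOD1-Veh and SOD1-Nec against WT-Veh in this order. The RIPK1 and necroptosis list held 3 tested members, none called (-0.17, 0.02 and 0.08). Interferon response genes (2 members) gave -0.54, 0.51 and -0.03, MHC class II genes (2 members) 1.36, -0.25 and 1.11, reactive astrocyte genes (2 members) -0.39, 0.53 and 0.15, and neutrophil and monocyte genes (3 members) 0.73, -1.84 and -1.19. The 4 haemoglobin genes gave -2.55, 3.65 and 1.10. Single members stood for the border macrophage list (Stab1; -0.29, -0.58 and -0.86), the endothelial list (Icam1; 0.40, -0.41 and -0.00), the neuron list (Meg3; -4.01, 2.72 and -1.29) and the sex-linked list (Ddx3y; 0.45, 0.14 and 0.60). Cholesterol synthesis and the T and NK cell list had no tested member.

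The share of microglia with a UMI followed the summed counts for several of these genes. With each cell thinned to 500 UMIs, which kept 133 microglia of WT-Veh, 118 of SOD1-Veh and 137 of SOD1-Nec, Lpl was seen in 0.794% ± 1.12, 10.1% ± 1.19 and 16.4% ± 7.76 of cells (SD, n = 2), against 0%, 1.19% and 3.15% of B cells, which should lack it. Of B cells thinned alike, at most 2.73% had a UMI of Ccl3, Ccl4, Il1a, Spp1, Cst7 or Itgax, and 1 B cell of 49, 82 and 107 used had one of Tnf. In microglia Ccl4, a chemokine, was seen in 30.2% ± 2.24, 50.1% ± 2.41 and 53.0% ± 6.43 and Ccl3 in 38.2% ± 4.60, 55.8% ± 2.91 and 42.8% ± 5.31. Tnf was seen in 9.60% ± 4.60, 18.6% ± 0.164 and 12.1% ± 9.38, Il1a in 17.2% ± 1.91, 21.9% ± 2.17 and 15.9% ± 2.65, and Il1b in 2.30% ± 1.23, 0.926% ± 1.31 and 5.86% ± 0.545. Spp1 was seen in 0 of 133 WT-Veh microglia at this depth (1 of 198 without thinning, so a cell with few transcripts can be missed) and in 3.27% ± 2.01 and 6.55% ± 0.424 of the others, while Cst7 reached 1.56% and 2.84% and Itgax 2.49% and 2.84% after 0 of 133 in WT-Veh. Apoe was seen in 24.0% ± 2.47, 42.8% ± 7.53 and 48.8% ± 2.69 of microglia, but also in 35.7%, 27.9% and 28.9% of B cells, so this share does not set WT-Veh microglia apart from B cells. Free RNA scaled on haemoglobin was put at 6.69% and 6.22% of the Apoe UMIs of WT-Veh microglia, so these readings of the background differ. Il1b was likewise seen in 4.22%, 0% and 1.96% of B cells. These shares were not tested.

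The effects of genotype and of treatment share the SOD1-Veh libraries, which alone makes them run against each other. Across 1585 microglial genes their covariance was -0.155, lower than in any of 100 simulated sets with unchanged groups (-0.113 ± 0.00782, from -0.131 to -0.0925). Their correlation was -0.398, weaker than in any of those sets (-0.522 ± 0.0242, from -0.579 to -0.451), and 59.9% of genes had opposite signs against a simulated mean of 67.4%. The measures pointed different ways, so whether the effects oppose each other beyond the shared libraries was left open. The covariance also holds Meg3 and the haemoglobin genes, RNA of other cells that moved far in opposite directions in the 2 comparisons. It was not taken without them, so the excess cannot be read as opposed effects on microglial genes. Genes are not independent replicates, and the libraries of a class also share its free RNA. Among called genes, 3 rose with genotype and fell with treatment, Ftl1, Lrrc58 and the predicted gene Gm10116. The 5 genes that fell with genotype and rose with treatment were Meg3 and the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt. Apoe and Lpl were the 2 genes that rose in both comparisons, and none fell in both. No chance value is given for these counts, since the comparisons share libraries. Microglia had 19 and 7 calls by edgeR with genotype and 40 and 19 with treatment, and DESeq2 gave 17 and 33 in all.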

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

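The tests of immediate-early genes in other immune cells and within the clusters of microglia were chosen only after those results were seen, and so were the subtraction of free RNA and the contrasts over shared members; the prediction of the subtraction and the other tests were written before.

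Disease-associated genes stood out because they moved one way in microglia and the other way in several other classes, in every pair of libraries; none of these differences was tested. Each class was averaged over its own tested members of the list, which were 21 in microglia, 7 in B cells, 5 in erythroid cells, 14 in monocytes and 12 in neutrophils. For SOD1-Veh against WT-Veh the list moved by 1.19 in microglia, so the difference was 1.52 from B cells (which moved by -0.333), 1.35 from monocytes (-0.162) and 1.35 from neutrophils (-0.165); erythroid cells moved the same way as microglia (0.0414). For SOD1-Nec against WT-Veh it moved by 1.29, and the difference was 1.74 from B cells (-0.442), 1.62 from erythroid cells (-0.321) and 1.52 from monocytes (-0.226), while neutrophils (-0.0400) did not oppose microglia in every pair. Over the members tested in both classes these contrasts stayed opposite in every pair, except that of neutrophils for SOD1-Veh against WT-Veh (1.31 in microglia and -0.161). Free RNA in the amount scaled on haemoglobin is argued against, since the median of the list for SOD1-Veh against WT-Veh was 1.00 before and 1.02 after its subtraction (0.85 to 1.28 with single libraries left out). That amount was 4.23% and 3.16% of microglial UMIs in WT-Veh and 0.763% and 1.77% in SOD1-Veh. A larger amount of free RNA was not tested and is left open. Another mix of the microglia clusters is argued against as the whole cause, since the medians were 0.81 (0.78 to 0.97) and 1.30 (1.12 to 1.41) within the clusters. A change of state in mutant microglia stays open as a hypothesis, as do differences of animals or dissection that 2 libraries per group do not separate from genotype.

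Immediate-early genes were flagged in the same way between SOD1-Nec and SOD1-Veh, again without a test of the difference: they moved by -0.442 in microglia, -0.990 below B cells (0.548) and -0.742 below monocytes (0.300). Tested members numbered 21 in microglia, 13 in B cells and 15 in monocytes, and over the shared members microglia moved by -0.487 and -0.501, still opposite in every pair. In monocytes, neutrophils and B cells together the median of the list was 0.23 (0.16 to 0.30 with single libraries left out) against -0.56 in microglia. The rise in B cells and monocytes had raised the flag, so their sum is no separate test of a weaker dissociation response of the whole SOD1-Nec library. The sum also takes in the larger share of monocytes in SOD1-Nec (13.1% of cells against 6.88%). Neutrophils, which were not flagged, moved by 0.0182, so the fall was not seen in them either. More shallow cells in SOD1-Nec are argued against, since the median was -0.49 (-0.61 to -0.44) with at least 400 genes per cell. Another mix of the microglia clusters cannot be told apart from lower expression within cells: the median was -0.00090 in 1 cluster (-0.35 to 0.57) and -0.55 in the other (-0.72 to -0.42), and the clusters were themselves formed in part by these genes. A response of microglia to dissociation that differs between groups, or an effect of the inhibitor, may each underlie it.

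Other lists moved oppositely in microglia and in another class in every pair of libraries, which no test addressed; 17 of 135 such contrasts did so in all, and 14 of the 17 over the members tested in both classes. These were 4 to 7 members in the contrasts below, against 7 to 26 in microglia alone. Homeostatic genes between SOD1-Nec and SOD1-Veh (-0.232 in microglia) differed by -0.606 from B cells (0.374) and by -0.436 from monocytes (0.203), and between SOD1-Nec and WT-Veh (-0.569) by -0.741 from B cells (0.171). The TNF and NF-kB list differed between microglia and neutrophils by 1.25 for SOD1-Veh against WT-Veh (0.267 and -0.981) and by -0.701 for SOD1-Nec against SOD1-Veh (-0.197 and 0.503), but over 5 shared members neither stayed opposite in every pair. For SOD1-Nec against SOD1-Veh, complement genes differed from neutrophils by -0.742 (-0.387 and 0.355), lysosome genes from neutrophils by -0.981 (-0.178 and 0.803) and stressed oligodendrocyte genes from erythroid cells by -0.827 (-0.326 and 0.501). Unfolded protein response genes for SOD1-Nec against WT-Veh differed from B cells by -0.446 (-0.247 and 0.199).

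Skeletal muscle RNA appeared in barcodes that no comparison of retained cells used. The 10 muscle genes, chosen from those leading the unnamed cluster, reached 616 and 3342 CPM there in the SOD1-Veh libraries, against 46.1 to 64.0 in the other 4 libraries.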

How the results depend on the processing

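Alternatives chosen after seeing the data were at least 100 genes per cell, up to 40% mitochondrial UMIs, free RNA subtracted, every barcode, neural and vascular classes only, no unnamed cluster, shares among neural and vascular cells, and the crossed block. In microglia 1500 of 1722 alternative values of 127 named results kept their direction and side of the threshold, 172 lost the call, 36 gained it and 14 changed sign. In all cells these were 655, 136, 16 and 27 of 834, in erythroid cells 105 of 138 kept it, in B cells 50 of 60, in monocytes 93 of 95 and in neutrophils 24 of 24. Apoe, Lgals3, Cd63 and Ftl1 in SOD1-Veh against WT-Veh were called in every alternative run (Apoe 2.07 to 2.72), and so was Ftl1 in SOD1-Nec against SOD1-Veh (-1.60 to -0.87); there Apoe ranged from 0.44 to 1.41. Of the shares of microglia with a UMI, 35 of 60 values moved by more than 1 SD with 300 UMIs or no thinning. Calls in a single library group assume that the lone library varies like the other groups.

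Counts by setting follow, each over SOD1-Veh against WT-Veh, SOD1-Nec against SOD1-Veh and SOD1-Nec against WT-Veh unless named; the cause was not tested where none is given. DESeq2 called 17, 33 and 48 genes in microglia and 7 in all cells of the last comparison. In microglia it gave no adjusted p to 645, 1167 and 1198 of 1585 genes, so its counts cover fewer genes; the named genes it is said not to call had an adjusted p. Without a low-count filter, when more genes share the adjustment, all cells gave 11, 10 and 0 genes (848 at an unadjusted p below 0.05 in edgeR) and the first comparison 10 lists. With at least 400 genes per cell, all cells of the first gave 40 genes, microglia of the second 30, the lists 5 in the second and the third, and shares 0 in the second; no class but microglia had enough cells, so other classes have no value. With at least 100 genes, other classes of the second gave 63 and shares of the second and the third 0. Doublets kept gave 1 share in the first, 0 in the third and 23 genes in other classes of the third. Up to 40% mitochondrial UMIs gave 19 genes in other classes of the third, 2 shares in the second and 4 in the third. Neural and vascular classes only gave 12, 0 (308 at an unadjusted p below 0.05) and 7 genes, no unnamed cluster 6, 0 (471) and 8, which removes the muscle genes by construction, every barcode 12 in the third, and the 4 libraries compared 1 in the third. An estimated correlation called 0, 0 and 0 lists in camera (3, 0 and 4 at an unadjusted p below 0.05) and fry 1, 0 (3) and 1, the homeostatic list each time (adjusted p = 0.0496 and 0.0139). Leiden resolution 0.5 gave 1 share in the first, TMM over classes 0 in the second, and shares among neural and vascular cells 0 in the second and the third. In edgeR, 0 to 3 classes had an unadjusted p below 0.05 where these share counts were 0. The labels do not pair libraries across groups by replicate number, yet tables of each number share a gene list; with the number as a block, all cells of the third gave 5 genes, the lists of the second 6, and shares 1 in the first and 0 in the third. Deviations of like-numbered libraries correlated at -0.27 and -0.37 across genes between WT-Veh and the SOD1 groups in all cells and at 0.23 between SOD1-Veh and SOD1-Nec, so pairing by number was left open; with the WT-Veh numbers crossed the block called 208 genes in the first and 53 in the third.

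With each library left out in turn, all cells gave 24 to 161, 24 to 55 and 1 to 53 genes, microglia 22 to 30, 35 to 54 and 42 to 66, other classes 22 to 56, 23 to 103 and 25 to 64, lists 5 to 9, 5 to 10 and 9 to 11, and shares 0 to 0, 0 to 1 and 0 to 5. The overlap of effects, beyond the simulated one, was -0.043 in covariance and -0.046 with the block. The correlation was weaker than the simulated mean in both (-0.398 against -0.522, and -0.403 against -0.524), as was the share of opposite signs (59.9% and 60.2% against 67.4%), so the measures differ in direction; the limit of 50 CPM removed no gene.

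Signs that changed were mostly of genes that did not pass; ranges are over single libraries left out. In all cells of SOD1-Veh against WT-Veh, Il1b ranged from -1.34 to 0.011 (without WT-Veh 1), Trem2 from -0.011 (without SOD1-Veh 1) to 0.40, and Ripk1 from -0.28 (without WT-Veh 2) to 0.86, with -0.22 without SOD1-Veh 1 and -0.19 with at least 400 genes. In SOD1-Nec against SOD1-Veh, Apoe ranged from -0.39 (without SOD1-Nec 2) to 0.45 and was -0.012 with doublets kept, -0.16 with up to 40% mitochondrial UMIs and -0.53 with every barcode. Ripk1 ranged from -0.60 to 0.27 (without SOD1-Veh 1), with 0.20 without SOD1-Nec 1, 0.26 with at least 400 genes and 0.088 with every barcode, where Sod1 was 0.16. In SOD1-Nec against WT-Veh, every barcode gave Apoe -0.036, Il1b 0.0097 and Trem2 0.031, and neural and vascular classes Il1b 0.90 and Trem2 0.017. There Il1b ranged from -0.88 to 0.45 (without WT-Veh 1), Tnf from -0.064 (without WT-Veh 1) to 0.37, with -0.016 without SOD1-Nec 1 and -0.0062 with at least 400 genes, Trem2 from -0.51 to 0.00021 (without SOD1-Nec 1), and Ripk1 from -0.42 (without SOD1-Nec 2) to 0.72, with -0.41 without WT-Veh 2 and -0.036 with at least 100 genes. In microglia of SOD1-Veh against WT-Veh, Il1b ranged from -2.41 to 0.17 (without WT-Veh 1), Trem2 from -0.037 (without SOD1-Veh 2) to 0.090, and Fabp5 from -0.24 (without SOD1-Veh 1) to a fitted 4.66 without WT-Veh 2, which left no WT-Veh UMI and bounds it at no less than -0.028, with -0.18 with at least 100 genes; with at least 400 genes Hba-a1 was 0.031 and Trem2 -0.061. In SOD1-Nec against SOD1-Veh, C3ar1 ranged from -1.61 to 0.064 (without SOD1-Nec 2) and S100a9 from -2.64 to 0.00021 (without SOD1-Veh 1), Mobp was -0.11 with at least 400 genes, and Hbb-bs was -1.33 after free RNA was subtracted, a correction scaled on haemoglobin. In SOD1-Nec against WT-Veh, Hbb-bt was then -0.59, Ftl1 ranged from -0.077 (without SOD1-Nec 2) to 0.56, Cd74 was -0.32 with up to 40% mitochondrial UMIs and S100a8 0.90 with at least 400 genes. The share of unnamed cells in SOD1-Nec against SOD1-Veh was 0.087 with at least 100 genes, since other clusters are then unnamed too. Depth limits genes such as Ripk1, Ripk3 and Mlkl, and changes near 2-fold, most of which the simulated data missed.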

Other observations

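Ribosomal protein genes were not among the lists written before the data were examined, and were taken as a set after the data were seen. Their test in the other classes was chosen only after the result was seen, as was the subtraction of free RNA as a setting.

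The monocyte class held cells of marrow type, led by genes of monocytes and of granulocyte precursors, and its granule genes followed the groups. Of 10 tested neutrophil and monocyte genes in this class, 4 fell in SOD1-Veh against WT-Veh and 4 rose in SOD1-Nec against SOD1-Veh; the medians were -0.45 and 0.18 and the means -1.87 and 1.34, since these 4 genes moved far and the others little.

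Small classes were also seen. T or NK cells made up 2.54%, 2.54% and 2.48% of WT-Veh, SOD1-Veh and SOD1-Nec cells, and endothelial cells 2.71% ± 1.07, 2.30% ± 0.308 and 3.13% ± 0.571 in the same order (SD, n = 2). Over all cells, 19 of 21 tested cell division genes were positive in SOD1-Veh against WT-Veh (median 0.51; 0.14 and 0.97 by set) and 20 of 21 in SOD1-Nec against WT-Veh (0.51; 0.03 and 1.21), with none called over all genes. The mix of cells moved with it, since B cells were 8.55%, 17.8% and 18.3% of WT-Veh, SOD1-Veh and SOD1-Nec cells and erythroid cells 11.7%, 14.2% and 17.6%. Within B cells the list had medians of 1.08 and 0.70 in these comparisons, within erythroid cells 0.25 and 0.09 and within microglia 0.02 and 0.04. How much the mix adds was not tested.

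Ribosomal protein genes were higher in SOD1-Nec than SOD1-Veh microglia: 20 of 79 rose, 72 were positive and the median log2 fold change was 0.48. Camera gave p = 5.5e-24, and 0.0574 with an estimated correlation. These p-values are not adjusted over lists, and they do not stand for a planned test, since the set was chosen from the same data. Free RNA in the amount scaled on haemoglobin is argued against by a median of 0.44 (0.40 to 0.68 with single libraries left out) after its subtraction. That amount was 0.763% and 1.77% of microglial UMIs in SOD1-Veh and 6.56% and 4.29% in SOD1-Nec, and a larger one was not tested. A shift of the whole library was tested as a hypothesis in the other tested classes together, whose median was 0.36 (0.30 to 0.41). So higher RNA of ribosomal protein genes was not seen in microglia alone, and may reflect a difference between libraries. Those classes were summed, and monocytes were 6.88% of SOD1-Veh and 13.1% of SOD1-Nec cells, so their mix may add to the rise. Whether the rise follows the inhibitor, the animals or the preparation was not tested. The same genes had a median of 0.60 in SOD1-Nec against WT-Veh and of 0.03 in SOD1-Veh against WT-Veh.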
